A study of Mus musculus with 12 samples.

How the data were processed

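RNA was extracted from freshly isolated islets, and poly(A) RNA was fragmented, and primed with random primers, per the labels' protocols, and libraries were sequenced as read pairs, per the labels. Reads were trimmed with Trimmomatic 0.36, aligned with STAR 2.5.2b to GRCm38 (mm10) and counted per gene with featureCounts of Subread 1.5.2, and DESeq2 was used, per the submitters' processing notes, which give these names without order or options. The annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. Without strand, reads of overlapping antisense genes cannot be told apart, and reads of close gene copies (Reg, histone, trypsinogen, kallikrein and ribosomal protein genes) can be shared among them.

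The deposited count table holds whole-number counts for 49315 Ensembl genes in 12 libraries, with different totals. The authors' deposited comparison table holds a normalized signal per library, the log2 fold change of anti-CD3 over IgG and its p-values. The deposited signal equals the counts divided by 1 size factor per library, since the ratio of both was constant over the genes of each library. The table's adjusted p is NA for 2935 genes and these were left as NA. Columns were matched to samples by the group and number in their names, 1 column of the count table carrying an unexplained prefix, and 0 columns of per-sample values were left unmapped. Gene symbols came from GENCODE M21 (GRCm38) for 48970 genes and from the authors' deposited table for 17, and 328 genes had none.

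Groups were taken from the sample titles, 6 IgG and 6 anti-CD3 libraries. Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 13115, and libraries were scaled by TMM. Because a few exocrine genes took most counts, TMM factors ran from 0.733 to 2.36. Counts outside the acinar genes, the depth left for all others, were 3280222 to 10956955 per library. The main test was edgeR's quasi-likelihood F test with robust estimation and Benjamini-Hochberg adjustment, at an adjusted p of 0.05. The SE of a log2 fold change was taken from the fold change and its F statistic. All tests were two-sided.

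Before the data were examined, 40 gene lists were fixed for immune cells, interferon and antigen presentation, endocrine cells, stress, and other cell types of the pancreas. Lists with at least 5 tested members were used, which left 36; germinal centre B cell, neutrophil and mast cell, adipocyte, and erythroid and platelet lists had 4, 1, 3 and 4 tested members. Lists were tested by camera on log2 CPM (prior count 2, preset correlation 0.01), by camera with an estimated correlation and by fry. Each library also received a score per list, the mean log2 CPM of its members, and scores were compared by an exact permutation test over 924 regroupings, with 0.00216 as the smallest p. The same test served 11 log2 ratios, where members shared by both lists were left out of the numerator. Correlations of scores used 100000 permutations for 12 libraries and every permutation within groups of 6.

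Named genes followed a rule fixed before the data were examined: up to 8 genes with the largest rise and up to 8 with the largest fall among those past the test with mean log2 CPM of at least 1, leaving out receptor segments and predicted genes; a panel of 30 genes; and the 2 members with the smallest p of each list that passed a test and of each endocrine or stress list. Of these the text gives values for part.

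The alternatives were DESeq2 1.42.0, limma-voom with quality weights, RLE and upper-quartile factors, TMM without immune, acinar, regenerating protein and hormone genes, 2 other filters on low counts, no robust estimation, the replicate number as a block, the acinar score as a covariate, a prior count of 0.5, medians in place of means, and each library left out in turn. Leaving out the libraries under 60% acinar counts (IgG 5 and IgG 6) and an offset for transcript length, a lowess trend with a span of 0.3 over the longest annotated transcript, were added after the data were examined.

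The procedure was tested on simulated data, with counts drawn for 12912 tested genes from the means and library sizes of these libraries. For anti-CD3 against IgG it recovered 55.1% of genes changed 2-fold and 85.9% of those changed 4-fold, with 6 unchanged genes called and 100% of calls in the right direction. The simulation gave every library the same mean profile and drew genes independently. It held no shared variation in acinar share, so these rates do not describe the test under the variation between the real libraries.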

Results

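The series measured polyadenylated RNA of pancreatic islets from female NOD/ShiLtJ mice, a strain that develops autoimmune diabetes as lymphocytes infiltrate the islets. Mice that still had normal blood glucose entered the study at 9 weeks of age and received a control IgG or an antibody against CD3, the signalling complex of the T cell receptor, once a week for 4 weeks. The anti-CD3 dose was 2.5 mg/kg, and islets were collected 2 to 3 days after the last dose. There were 6 IgG and 6 anti-CD3 libraries. The labels do not say whether each library came from 1 mouse or from a pool, so p-values measure the spread between these samples. Total counts ran from 11891132 to 17628347 per library in IgG and from 10994337 to 19284740 in anti-CD3. Of 49315 genes in the count table, 13115 passed the filter on low counts and were tested.

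Exocrine transcripts made up most of every library but 1. The 30 acinar genes, which encode digestive enzymes and other products of the exocrine pancreas, took 59.6% ± 14.8 of the counts in IgG (SD, n = 6) and a mean of 69.0% in the 6 anti-CD3 libraries (67.3% to 71.2%), a difference that did not exceed the spread (exact permutation test, two-sided, p = 0.0931). The spread in IgG came from IgG 5, with 54.5%, and IgG 6, with 31.9%, while the other libraries of both groups lay between 63.8% and 71.2%. Islet hormone genes took 2.26% ± 1.11 of the counts in IgG (SD, n = 6) and 1.51% ± 0.346 in anti-CD3 (SD, n = 6; exact permutation p = 0.171). This set held Ins1, Ins2, Gcg, Sst, Ppy, Pyy, Iapp and Ttr, the last a transport protein gene and not a hormone gene. IgG 6 also had a count for 25828 genes, against at most 20143 in the other IgG libraries.

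**Figure D1:**
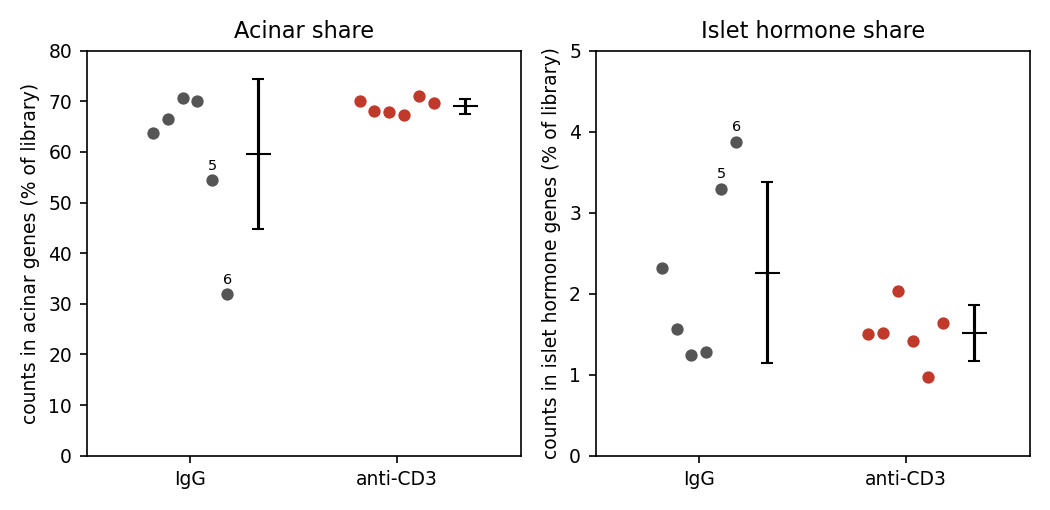
Percentage of each library's counts in the 30 acinar genes (left) and in the 8 genes of the islet hormone set, Ttr included (right), by group. Each point is 1 library, the bar is the mean with its SD (n = 6 per group), and IgG 5 and IgG 6 are numbered; IgG 6 has the lowest acinar share, 31.9%.

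The comparison of anti-CD3 with IgG asks how the antibody treatment changed the islet transcriptome. In anti-CD3 islets 10 genes rose and 0 fell (edgeR quasi-likelihood test, adjusted p under 0.05), and 7 of the 10 changed at least 2-fold. The largest rises among the 10 were in histone genes. Hist1h1c, a linker histone, rose by 2.09 ± 0.27 on the log2 scale (SE, n = 6 per group; edgeR adjusted p = 0.0221), or 4.25-fold. H1f0, a replacement linker histone, rose by 1.69 ± 0.26 (SE; edgeR adjusted p = 0.0402), Hist1h2bc by 1.27 ± 0.21, and H3f3b, which encodes the replacement histone H3.3, by 1.15 ± 0.18. Cox7b and Cox7c, subunits of cytochrome c oxidase in the respiratory chain, rose by 1.10 ± 0.16 and 0.95 ± 0.16. Enpp1, an ectoenzyme that hydrolyses extracellular nucleotides, rose by 1.02 ± 0.18, and Ost4, a small subunit of the oligosaccharyltransferase of the endoplasmic reticulum, by 0.85 ± 0.14. In each of these 8 genes, all 6 anti-CD3 libraries lay above the IgG mean. The others were Ube2b, a ubiquitin-conjugating enzyme, at 0.69, and the predicted gene Gm6472 at 1.15, both named here after their values were seen. With an offset for transcript length, also chosen after the data were seen, Cox7c was at 0.49 ± 0.11, Ost4 at 0.55 ± 0.12 and Gm6472 at 0.70 ± 0.16 (SE; edgeR adjusted p = 0.112 for each). Hist1h2bc, at 0.98 ± 0.17, and H3f3b, at 1.09 ± 0.17, did not pass with it either (SE; edgeR adjusted p = 0.0652 and 0.0517), nor did Ube2b, at 0.55 ± 0.10 (SE).

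On GRCm38, Hist1h1c (ENSMUSG00000036181) spans 23738808 to 23740367 and Hist1h2bc (ENSMUSG00000018102) spans 23684199 to 23692908, both on chromosome 13. H1f0 (ENSMUSG00000096210) lies on chromosome 15 from 79028450 to 79030504, and H3f3b (ENSMUSG00000016559) on chromosome 11 from 116021912 to 116027962. Cox7b (ENSMUSG00000031231) lies on chromosome X from 106015700 to 106022450, Cox7c (ENSMUSG00000017778) on chromosome 13 from 86044816 to 86046904, Enpp1 (ENSMUSG00000037370) on chromosome 10 from 24637914 to 24712159, and Ost4 (ENSMUSG00000038803) on chromosome 5 from 30905885 to 30907788. All 8 are annotated as protein-coding, and the values sum reads over each gene. Histone genes have near-identical copies and the handling of reads that map to several places is not given in the sources used here, so the share of each copy is uncertain. Poly(A) RNA was sequenced, so the histone values cover polyadenylated transcripts and do not measure total histone RNA.

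**Figure D2:**
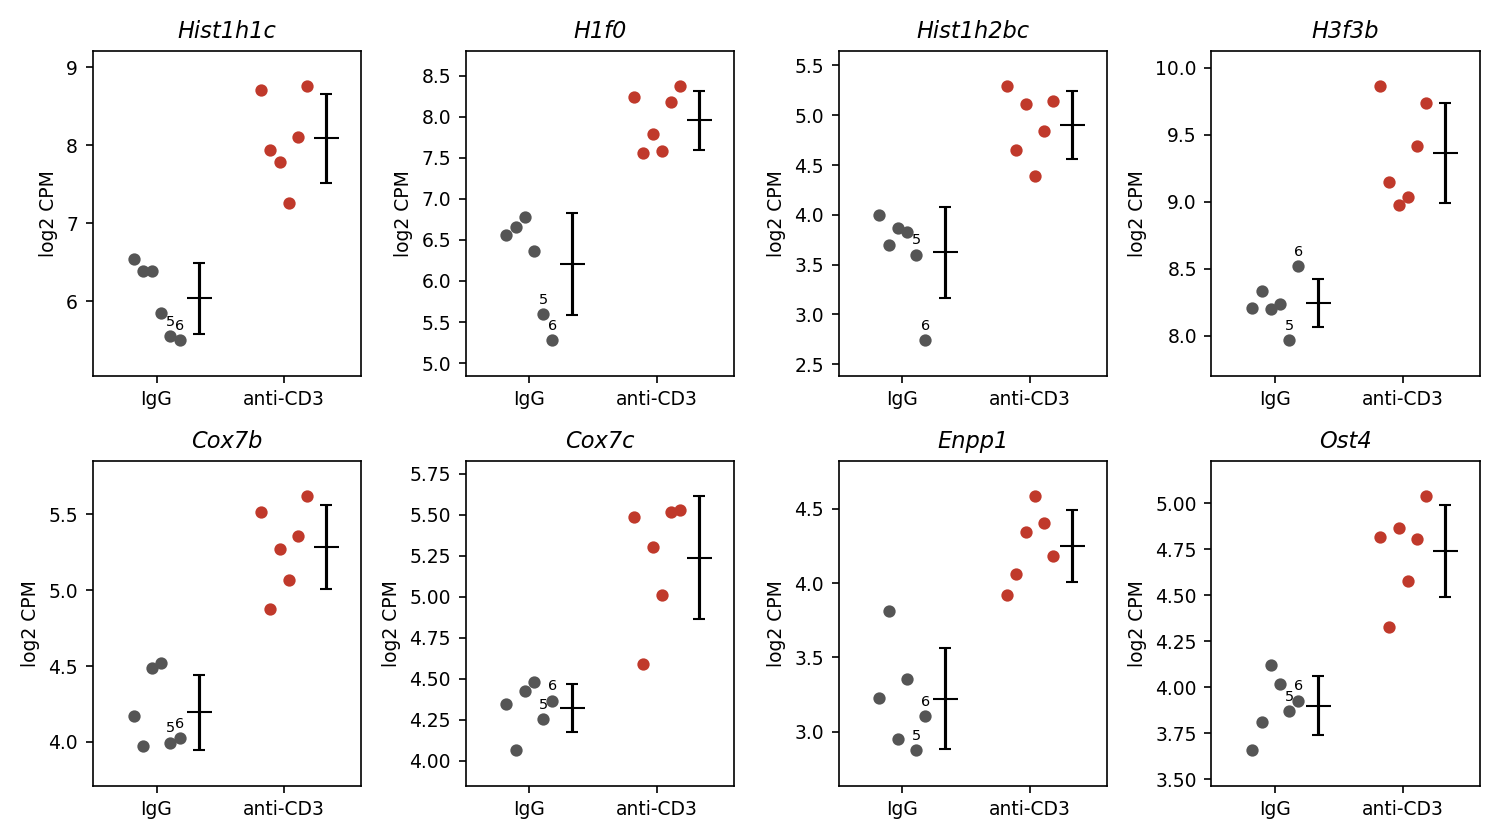
Log2 CPM of the 8 named genes with the largest rises among genes past the edgeR test, predicted genes left out, by group. Each point is 1 library and the bar is the mean with its SD (n = 6 per group); for Hist1h1c all 6 anti-CD3 libraries lie above all IgG libraries.

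The number of changed genes depended on the test and on single libraries. It was 454 with DESeq2 (319 higher, 135 lower), and 0 with the acinar score as a covariate or with the replicate number as a block. Leaving out 1 library gave between 0 (without IgG 5, anti-CD3 1, anti-CD3 5 or anti-CD3 6) and 203 (without anti-CD3 2). With the block the 8 named genes had values between 0.84 (Ost4) and 2.05 (Hist1h1c). With the covariate the 8 named genes had values between 0.80 ± 0.17 (Ost4) and 1.75 ± 0.29 (Hist1h1c; SE). Without IgG 5 and IgG 6, an alternative chosen after the data were seen, 1 gene passed, H1f0, and the 8 named genes had values between 0.85 (Ost4) and 1.87 (Hist1h1c). At an unadjusted p under 0.05 there were 2408 genes, 1270 higher and 1138 lower, where 656 would be found with no change. Of 100 splits of the 12 libraries, the real one included, 2 gave as many. The other gave 2499 and was the real one with IgG 1 and anti-CD3 2 exchanged. The groups did not overlap for 158 genes that were higher and 84 that were lower in anti-CD3, and chance gives 0.216% of genes.

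Regenerating proteins, secreted lectin-type proteins of the exocrine pancreas and gut that are induced by injury and inflammation, showed the largest difference of any list. All 6 measured members were higher in anti-CD3, with a median log2 fold change of 2.72. Reg3b was higher by 3.04 ± 0.71 (SE, n = 6 per group; edgeR adjusted p = 0.0769) and Reg3g by 2.83 ± 0.69 (SE; edgeR adjusted p = 0.0866). Over all genes tested 0 of the 6 passed, and 6 passed when adjusted over the list alone, at an unadjusted p under 0.05 and with DESeq2. The mean log2 CPM of the list was 5.99 ± 1.70 in IgG (SD, n = 6) and 8.81 ± 0.65 in anti-CD3 (SD, n = 6), with no overlap between the groups. Its exact permutation p was 0.00216, the smallest that 924 regroupings can give, and 0.0779 after adjustment over 36 lists. The list passed camera with a preset correlation (adjusted p = 5.86e-07) and not otherwise (adjusted p = 0.668 with an estimated correlation). Reg genes lie in a family of close copies, so reads can be shared among them. The median was 2.20 without IgG 5 and IgG 6 and 1.29 with the acinar score as a covariate, where the list passed camera (adjusted p = 1.61e-06).

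The acinar list moved the same way. Of its 30 members 29 were higher in anti-CD3, the median log2 fold change was 0.68, and 0 passed edgeR over all genes or adjusted over the list alone (9 at an unadjusted p under 0.05, 0 with DESeq2). Prss2, a trypsinogen, was higher by 0.95 ± 0.36 and the amylase gene Amy2b by 0.93 ± 0.36 (SE; edgeR adjusted p = 0.190 and 0.198). Cpa1, a carboxypeptidase, was at 0.43 ± 0.36, or 0.23 without IgG 6. The list passed camera (adjusted p = 1.01e-10; adjusted p = 0.733 with an estimated correlation), and its score did not pass after adjustment (exact permutation p = 0.0195, adjusted p = 0.175). The median was 0.32 without IgG 5 and IgG 6 and 0.37 with the length offset, and the list passed camera in both.

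Lists of the respiratory chain, of endoplasmic reticulum stress and of immediate early genes had higher values in anti-CD3 islets, and their camera calls did not hold with an estimated correlation. All 22 nuclear-encoded oxidative phosphorylation genes were higher, with a median of 0.52. Over all genes 0 passed edgeR and 6 passed DESeq2, and 17 passed adjusted over the list alone or at an unadjusted p under 0.05, among them Cox7a2 at 0.87 ± 0.18 and Ndufa1, a subunit of complex I, at 0.85 ± 0.17 (SE, n = 6 per group). Camera gave an adjusted p = 3.09e-11 (adjusted p = 0.668 with an estimated correlation). The 9 tested mitochondrially encoded genes were also all higher, with a median of 0.27 (camera adjusted p = 0.0255, and adjusted p = 0.733 with an estimated correlation). Of these 0 passed edgeR over all genes, adjusted over the list alone or at an unadjusted p under 0.05, and 0 passed DESeq2. Before scaling, mitochondrial genes went the other way, with 0.645% ± 0.169 of the counts in IgG and 0.548% ± 0.094 in anti-CD3 (SD, n = 6 each, exact permutation p = 0.245). Of 24 endoplasmic reticulum stress genes, 22 were higher, with a median of 0.47 (camera adjusted p = 7.54e-08; adjusted p = 0.668 with an estimated correlation). Of these 10 passed adjusted over the list alone and 0 over all genes with edgeR, against 12 at an unadjusted p under 0.05 and 7 with DESeq2. Atf3, a stress-induced transcription factor, was higher by 1.59 ± 0.32, Ddit3, the transcription factor CHOP, by 1.51 ± 0.27, and Hspa5, the chaperone BiP, by 0.51 ± 0.19 (edgeR adjusted p = 0.0659, 0.0646 and 0.179). Of 18 immediate early genes, which respond to tissue dissociation among other stimuli, 16 were higher, with a median of 0.52 and 8 passing adjusted over the list alone, 0 over all genes with edgeR and 4 with DESeq2 (camera adjusted p = 6.02e-06; adjusted p = 0.715 with an estimated correlation). Btg2 was higher by 1.05 ± 0.26. Per library, the score test gave exact permutation p = 0.00866 for oxidative phosphorylation, 0.00433 for endoplasmic reticulum stress and 0.0368 for immediate early genes, and none passed adjustment (adjusted p = 0.104, 0.0779 and 0.265). The medians of these 3 lists were 0.40, 0.31 and 0.48 without IgG 5 and IgG 6. That of oxidative phosphorylation was 0.26 with the length offset and that of endoplasmic reticulum stress 0.25 with the acinar score as a covariate, and both lists passed camera there. The mitochondrially encoded list did not pass camera without IgG 1 (median 0.21), without IgG 6 (0.20) or without IgG 5 and IgG 6 (0.13, adjusted p = 0.357). Nor did it pass with the acinar covariate (0.051) or with the length offset (-0.014, adjusted p = 0.998). With a filter of CPM above 1 in 6 libraries it did not pass either (0.20, camera adjusted p = 0.0507).

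**Figure D3:**
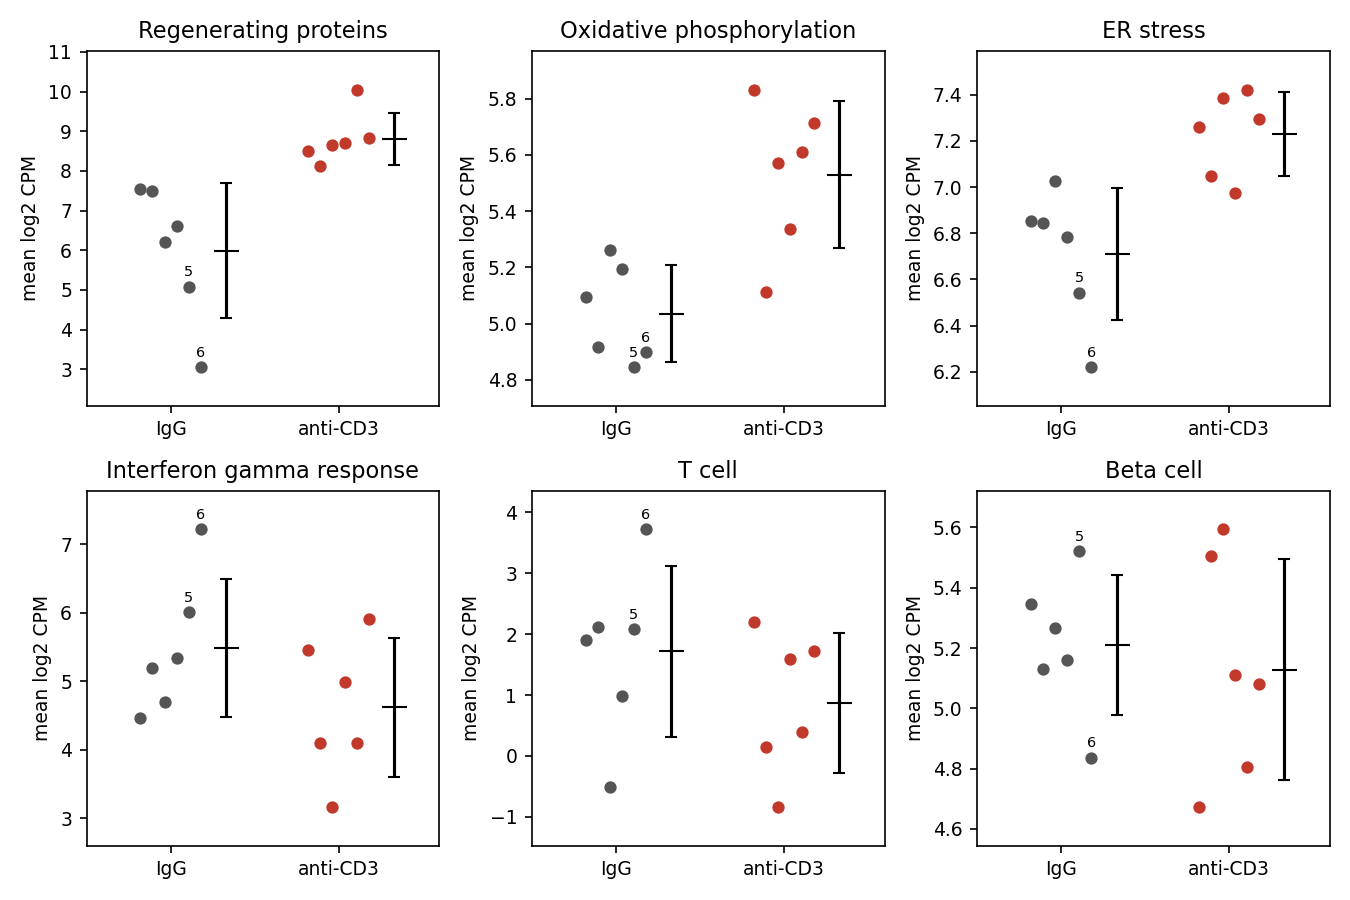
Mean log2 CPM of 6 gene lists per library, by group. Each point is 1 library, the bar is the mean with its SD (n = 6 per group), and IgG 5 and IgG 6 are numbered; the regenerating protein scores do not overlap between groups, and IgG 6 has the highest T cell and interferon gamma response scores.

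Immune and interferon genes had lower values in anti-CD3, with a spread between libraries that was larger than the difference. All 27 T cell genes were lower, with a median of -1.16, and 0 passed edgeR over all genes or adjusted over the list alone (6 at an unadjusted p under 0.05, 0 with DESeq2). Cd3e, a chain of the antibody's target, was at -1.51 ± 0.54, Cd8a at -1.59 ± 0.68 and Cd4 at -1.24 ± 0.77 (SE, n = 6 per group; edgeR adjusted p = 0.182, 0.245 and 0.400). Without IgG 6, Cd8a was at -1.05 and Cd4 at -0.31. The T cell score was 1.72 ± 1.40 in IgG and 0.87 ± 1.16 in anti-CD3 (SD, n = 6 each; exact permutation p = 0.288, adjusted p = 0.545). All 21 interferon gamma response genes were lower, with a median of -0.95, including Cd274, the checkpoint ligand PD-L1, at -1.25 ± 0.51, or -0.77 without IgG 6. All 24 type I interferon genes (median -0.76), all 10 MHC class II genes (median -1.16), 17 of 18 MHC class I genes (median -0.63), all 17 macrophage genes (median -0.83) and all 12 dendritic cell genes (median -0.71) were lower. In these lists and the interferon gamma list 0 passed edgeR over all genes or adjusted over the list alone, 1 to 3 per list were lower at an unadjusted p under 0.05, and 0 passed DESeq2. The exception among MHC class I genes was Psmb10, an immunoproteasome subunit, at 0.59 ± 0.21. Camera called these 7 lists lower, with adjusted p from 8.23e-05 for interferon gamma response to 0.0318 for macrophages. None held with fry or with an estimated correlation, which gave adjusted p = 0.797 for macrophages and adjusted p = 0.733 for the other 6. At the preset correlation all 7 passed camera with the replicate number as a block and with the length offset.

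The immune difference moved with the libraries of low acinar share. Without IgG 5 and IgG 6 the median of the T cell list was -0.29, that of interferon gamma response -0.07 and that of type I interferon 0.02, and none of the 7 lists passed camera. Without IgG 6 alone, 2 of the 7 passed, the type I interferon and interferon gamma response lists. With the acinar score as a covariate none of the 7 passed camera, with medians from -0.03 for interferon gamma response to 0.45 for MHC class II. Camera calls are also made by regrouping: in 56 of 100 splits of the 12 libraries, the real one included, at least 14 lists passed.

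**Figure D4:**
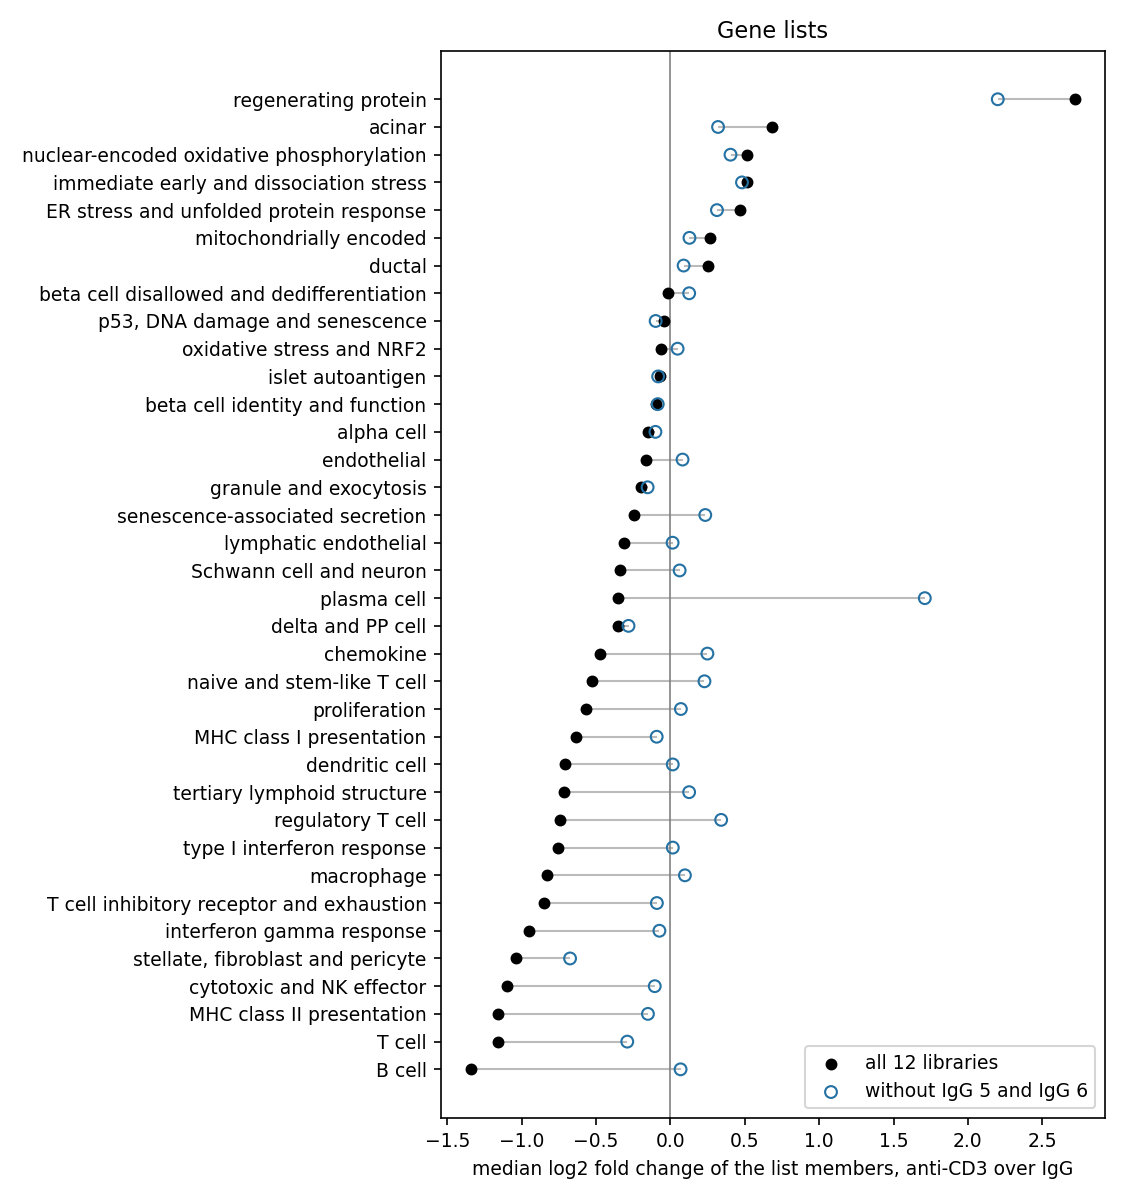
Median log2 fold change, anti-CD3 over IgG, of the tested members of 36 gene lists with all 12 libraries (filled) and without IgG 5 and IgG 6 (open). The regenerating protein list stays highest, at 2.72 and 2.20, and the T cell list goes from -1.16 to -0.29.

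Other immune lists did not pass camera in the main test. B cell genes had a median of -1.34, cytotoxic and natural killer genes -1.10, inhibitory receptor genes -0.85 and regulatory T cell genes -0.74. Tertiary lymphoid structure genes were at -0.72, naive and stem-like T cell genes at -0.53 and chemokine genes at -0.47. In the same order, these medians were -0.30, -0.45, -0.30, -0.04, -0.05, -0.04 and 0.19 without IgG 6 alone. For plasma cells the measures differed in sign, with a median of -0.35 and a mean of -0.49 over genes against a score difference of 0.55 and an upward camera direction (adjusted p = 0.271). The plasma cell list passed camera as higher without IgG 6 (median 1.09, adjusted p = 0.0123), without IgG 5 and IgG 6 (1.71, adjusted p = 4.88e-05) and with the acinar covariate (2.16). With 1 library left out, the cytotoxic list passed camera as lower in 7 of 12 omissions, the B cell list in 5, inhibitory receptor in 4, chemokine in 2 and regulatory T cell in 1, with medians of -1.87, -1.60, -1.15, -0.65 and -0.97 at the lowest. The cytotoxic list also passed with the replicate number as a block (adjusted p = 0.00231) and with the length offset (adjusted p = 0.0162), and the B cell list with the block (adjusted p = 0.0183). With the acinar covariate the B cell and regulatory T cell lists passed camera in the opposite direction, as higher (medians 0.68 and 0.62, adjusted p = 0.0332 for both). Among the panel, Foxp3 was at -0.81 ± 0.64, Gzmb at -2.02 ± 0.94, Ptprc at -1.34 ± 0.80, Cxcl9 at -0.97 ± 0.69, Cxcl10 at -0.83 ± 0.73, B2m at -0.50 ± 0.50, H2-K1 at -0.68 ± 0.35 and H2-Ab1 at -1.06 ± 0.68 (SE). Without IgG 6 alone, Foxp3 was at -0.06, Gzmb at -0.75, Ptprc at -0.43, Cxcl9 at -0.05, Cxcl10 at 0.09, B2m at -0.03, H2-K1 at -0.39 and H2-Ab1 at -0.21. Of these, Foxp3, Cxcl9, Cxcl10 and B2m had positive values without IgG 5 and IgG 6. Ifng did not pass the filter on low counts, with 631 of its 666 IgG counts in IgG 6 and 38 counts over the 6 anti-CD3 libraries.

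Stromal genes were lower in anti-CD3. All 19 genes of stellate cells, fibroblasts and pericytes had negative values, with a median of -1.04, and 7 passed adjusted over the list alone and 0 over all genes with edgeR, against 10 at an unadjusted p under 0.05 and 3 with DESeq2. The collagen genes Col3a1 and Col6a3 were at -1.37 ± 0.44 and -1.21 ± 0.35 (SE, n = 6 per group; edgeR adjusted p = 0.146 and 0.112). Camera called the list lower (adjusted p = 2.71e-05; adjusted p = 0.733 with an estimated correlation), and its exact permutation p was 0.0541 (adjusted p = 0.325). Without IgG 5 and IgG 6 the median was -0.68 and the list passed camera (adjusted p = 0.00281), while with the acinar covariate it was -0.36 and the list did not pass (adjusted p = 0.0974). Ductal genes (median 0.25), endothelial genes (-0.17), lymphatic endothelial genes (-0.31) and Schwann cell and neuron genes (-0.34) did not pass in the main test. In the same order, these medians were 0.21, 0.06, -0.02 and -0.04 without IgG 6. The ductal list passed as higher without IgG 3 (0.43), while its median was 0.09 without IgG 5 and IgG 6.

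Scores of the endocrine lists did not differ by more than the spread between libraries. The 29 tested genes of beta cell identity and function had a median of -0.10, and the score was 5.21 ± 0.23 in IgG and 5.13 ± 0.37 in anti-CD3 (SD, n = 6 each; exact permutation p = 0.639). Ins1 was at -0.12 ± 0.25, Ins2 at 0.27 ± 0.24, Mafa at 0.78 ± 0.38, Pdx1 at -0.44 ± 0.17, Slc2a2 at -0.37 ± 0.32 and Ucn3 at -0.28 ± 0.22 (SE). Gcg, the glucagon gene, was at 0.05 ± 0.26 and Sst, the somatostatin gene, at -0.38 ± 0.27. The sign of Ins1 changed without IgG 1 (0.16) and that of Gcg without IgG 1, IgG 3, anti-CD3 1 or anti-CD3 6 (-0.05 at the lowest). Without IgG 5, Slc2a2 was at -0.18 and Ucn3 at -0.09, without IgG 1 Sst was at -0.17, and without anti-CD3 3 Ins2 was at 0.14 and Mafa at 0.49. List medians were -0.15 for alpha cells, -0.35 for delta and PP cells, -0.07 for islet autoantigens, -0.20 for granule and exocytosis genes and -0.02 for disallowed and dedifferentiation genes. In the main test none passed camera, over all genes or adjusted over the list alone. The granule and exocytosis list passed camera as lower without IgG 4, IgG 6, anti-CD3 2 or anti-CD3 3 (median -0.29 at the lowest). It also passed with the length offset (-0.23, adjusted p = 0.0230). It did not pass without IgG 5 and IgG 6 (-0.15, adjusted p = 0.136) or with the acinar covariate (-0.18, adjusted p = 0.0974). The delta and PP cell list passed as lower with the length offset (-0.36, adjusted p = 0.0134). The disallowed and dedifferentiation list passed as higher with the acinar covariate (0.28, adjusted p = 0.0402). Sstr3, a somatostatin receptor, was at -0.76 ± 0.23 (SE; edgeR adjusted p = 0.122) and Chgb, a granule protein, at -0.66 ± 0.25, or -0.32 without IgG 1. In Sstr3 and Pdx1, 0 of 6 anti-CD3 libraries lay above the IgG mean.

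Further stress lists did not pass camera in the main test. Median values were -0.04 for p53, DNA damage and senescence, where Cdkn1a was at 0.19 ± 0.17 and Trp53inp1 at 0.73 ± 0.21, and -0.24 for the senescence-associated secretion list. They were -0.57 for proliferation, where Mki67 was at -1.18 ± 0.60 (-0.59 without IgG 6), and -0.06 for oxidative stress. In the latter 2 genes fell when adjusted over the list alone, Txnrd1 at -0.48 ± 0.13 and Srxn1 at -0.73 ± 0.20 (SE), both antioxidant enzymes. Over all genes 0 members of the oxidative stress list passed edgeR and 2 passed DESeq2 as lower. With the acinar covariate the secretion and proliferation lists passed camera as higher (medians 0.46 and 0.51, adjusted p = 0.0332 for both), and without IgG 4 the proliferation list passed as lower (-0.78). Cdkn2a did not pass the filter on low counts.

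Of 11 ratios within the infiltrate or the islet, 0 passed adjustment. The naive and stem-like to T cell ratio was higher by 0.61 on the log2 scale (exact permutation p = 0.0195, adjusted p = 0.214) and the regulatory T cell to T cell ratio by 0.50 (exact permutation p = 0.0563, adjusted p = 0.310). Cd8a to Cd4 was at -0.85 (exact permutation p = 0.0866, adjusted p = 0.317). Over the 12 libraries the T cell score and the beta cell score had a Pearson r of -0.49 (permutation p = 0.104) and a Spearman rho of -0.49 (permutation p = 0.110). Within groups r was -0.45 in IgG (exact permutation p = 0.356) and -0.74 in anti-CD3 (exact permutation p = 0.114), with adjusted p = 0.171 at the lowest over these 3 relations. Without anti-CD3 3 and IgG 3, the libraries farthest from the median T cell score, r was -0.31.

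The authors' deposited table lists 13703 genes, of which 490 had an adjusted p under 0.05, 349 higher and 141 lower in anti-CD3. Of these, 91 in the authors' deposited table changed at least 2-fold, 65 higher and 26 lower. All 10 genes that passed edgeR were among the 490, and across the 13093 genes in both, log2 fold changes had a Pearson r of 0.9998. The authors' deposited table called 6 of 6 regenerating protein genes, 7 endoplasmic reticulum stress genes and 8 oxidative phosphorylation genes higher. The authors' deposited table gave Reg3b a log2 fold change of 3.04 with an adjusted p = 0.00195 and Ddit3 1.51 with an adjusted p = 8.72e-05. Col1a1, Col3a1, Col6a3, Sstr3 (adjusted p = 0.0464), Txnrd1 (adjusted p = 0.00914) and Srxn1 (adjusted p = 0.0221) were called lower in the authors' deposited table. Of the 30 acinar genes, 1 was called higher in the authors' deposited table, Prss2 (adjusted p = 0.0468), and 0 T cell genes were called.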

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

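Tests chosen only after the result was seen are those of the ribosomal protein list, of the principal transcript length, of the length offset, of the omission of IgG 5 and IgG 6, of the omission of IgG 6 for immune and stromal lists apart, and of the regenerating protein score minus the acinar score.

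In each group of 6 libraries, library measures, list scores, ratios and named genes were searched for a library whose gap to the nearest other exceeded Dixon's critical share of the range. This held in 11 of 262 groups, and chance gives about 13. IgG 6 stood apart in the number of genes with a count, 25828 against 18650 to 20143 (gap 0.792 of the range), in counts outside acinar genes, 10956955 against 4157609 to 6373451 (0.674), and in Hist1h2bc, at 2.74 log2 CPM against 3.60 to 4.00 (0.681). IgG 1 was highest in its group for Ddit3 (0.637) and Chgb (0.639). Among anti-CD3 libraries, anti-CD3 3 was lowest for the beta cell disallowed and dedifferentiation score (0.643) and highest for Gc (0.656) and mt-Cytb (0.771). Anti-CD3 5 was highest for the regenerating protein score, 10.05 against 8.13 to 8.82 (0.640), and for Bbc3 (0.738). Anti-CD3 4 was lowest for Hspa5, 10.23 against 10.60 to 10.82 (0.634).

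The 10 genes past edgeR were set against regrouping. Of 100 splits of the 12 libraries, 2 gave as many genes, the real one and another with 10, and the same 2 gave at least 7 genes changed 2-fold (10 in the other). For both counts the share of drawn splits with as many was thus under 0.05. The draw covered only part of the possible splits, and the genes changed 2-fold are among the 10. The rule fixed before this test took a share under 0.05 as evidence against regrouping. The other split was the real one with IgG 2 and anti-CD3 3 exchanged, so it shares most of the real contrast. As the draw was partial and this split matched the count and exceeded that of genes changed 2-fold, chance is not excluded. Nor is it for the 14 lists past camera, since 56 of the 100 splits gave as many and the highest other gave 29.

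Lower immune and interferon lists in anti-CD3 may rest in large part on IgG 6: over the 7 lists, the median without IgG 6 was 0.273 of that with all libraries (-0.23 against -0.83), and 2 of the 7 passed camera. The stromal list rested on it less, with a median of -0.69 without IgG 6, or 0.665 of that with all libraries, and a camera adjusted p = 0.00111 (exact permutation p of the score 0.139). Dilution by acinar RNA cannot be told apart from a smaller infiltrate: the mean score of these 8 lists minus the beta cell score differed by -0.66 (exact permutation p = 0.355), with an interval of -2.19 to 0.83 that holds both 0 and the whole difference of -0.74. An effect of the antibody on the infiltrate stays open.

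Higher regenerating protein genes in anti-CD3 were weighed against more acinar RNA and against the low acinar share of IgG 5 and IgG 6. The regenerating protein score minus the acinar score was -5.27 ± 0.97 in IgG and -3.34 ± 0.57 in anti-CD3 (SD, n = 6 each; exact permutation p = 0.00216, the smallest possible), so acinar RNA alone does not account for it. With the acinar score as a covariate the list's median went from 2.72 to 1.29 and the list passed camera (adjusted p = 1.61e-06), so acinar RNA may account for part. When IgG 5 and IgG 6 were left out the difference of the regenerating protein score itself was 1.85, or 0.658 of its size, and that of the score minus the acinar score 1.54, both with an exact permutation p = 0.00476, the smallest that 210 regroupings give. A response of exocrine cells to the antibody is a hypothesis that these data leave open, as is a difference in islet isolation between groups, which the labels do not record.

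Ribosomal protein and oxidative phosphorylation genes, 103 in all, were higher in anti-CD3 with a median of 0.73, and their transcripts are short (median 751 bases by principal transcript against 2845 for all tested genes). Libraries differed in a trend with transcript length (mean rho 0.16 in IgG and -0.14 in anti-CD3, exact permutation p = 0.0390), so length may account for part of the difference. Against 10000 random lists matched on length, the median was higher by 0.477 with the principal and 0.542 with the longest transcript. The median of 0.73 lay above the upper limits of 0.34 and 0.27 for the medians of the random lists. Those lists drew genes independently, while genes of this pattern move together (estimated correlation 0.583 for oxidative phosphorylation). The spread of the random lists is thus too narrow to test the difference. The fewest genes in a length bin drawn from were 2 by principal and 33 by longest transcript. A length offset lowered the median to 0.32 and 0.41. With IgG 5 and IgG 6 left out the median was 0.886 of its size (0.64, exact permutation p = 0.0238). RNA quality was not recorded in the labels, and an effect of the antibody stays open.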

How the results depend on the processing

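Tests chosen only after the result was seen are those without IgG 5 and IgG 6 and with the length offset. Counts of changed genes depended on the setting, while most directions did not. The 10 genes (7 changed at least 2-fold) became 454 (105) with DESeq2, 135 (30) with limma-voom, 167 (35) without the filter on low counts, 5 (4) without robust estimation and 6 with upper-quartile factors. They became 4 (3) with the length offset, 1 (1) without IgG 5 and IgG 6, and 0 (0) with the acinar score as a covariate, where 1239 genes had an unadjusted p under 0.05. Each count by DESeq2, limma-voom and no filter held all 10 genes. RLE factors and TMM without composition genes gave 7, and the other filter gave 10. Leaving out 1 library gave 0 to 203 genes and 0 to 50 changed at least 2-fold: 0 without IgG 5, anti-CD3 1, anti-CD3 5 or anti-CD3 6, 1 without anti-CD3 3, 2 without IgG 1, 3 without IgG 4, 4 without IgG 3, 5 without IgG 6, 6 without anti-CD3 4, 7 without IgG 2, and 203 without anti-CD3 2. Of 36 lists 14 passed camera, 0 with an estimated correlation, 0 with fry, 7 without IgG 5 and IgG 6, 10 with the acinar covariate and 10 to 20 with 1 library left out. List scores past the exact test numbered 0, and 2 without IgG 3 (endoplasmic reticulum stress and regenerating protein), while ratios stayed at 0 in each setting run. The overlap with the authors' deposited table was 10 genes, 436 with DESeq2 and 0 at an adjusted p under 0.01 in both. The cause was not tested for these counts. Counts outside acinar genes, 3280222 to 10956955 per library, limit the precision for islet and immune genes.

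Same-numbered libraries had correlations of 0.063, 0.13, 0.55, -0.20, -0.29 and 0.54 in their deviations, and 3 of 6 numbers correlated best with their own. Whether the numbers pair the samples cannot be told from this. With the replicate number as a block, 0 genes passed edgeR (0 at least 2-fold; 2716 at an unadjusted p under 0.05) and 16 lists passed camera. Medians of plasma cell 0.22 and dedifferentiation 0.038 changed sign with the block.

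With the acinar score as a covariate, signs reversed for the genes Ptprc 0.34, B2m 0.40, Foxp3 0.58, Cxcl9 0.56, Cxcl10 0.61, Cpa1 -0.21, Cd4 0.45, Gzmb 0.23, H2-Ab1 0.51, Tyrobp 0.17, Timp2 0.17 and Tpx2 0.26. List medians reversed for T cell 0.15, cytotoxic 0.29, regulatory T cell 0.62, inhibitory receptor 0.30, naive T cell 0.45, B cell 0.68, plasma cell 2.16, macrophage 0.44, dendritic cell 0.36, chemokine 0.57, tertiary lymphoid structure 0.60, type I interferon 0.14, MHC class I 0.097, MHC class II 0.45, dedifferentiation 0.28, secretion 0.46, proliferation 0.51, ductal -0.12, endothelial 0.30, lymphatic endothelial 0.20 and Schwann cell 0.17. Of these, the regulatory T cell, B cell, plasma cell, dedifferentiation, secretion and proliferation lists passed camera as higher in anti-CD3. The cause was not tested.

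When IgG 5 and IgG 6 were left out, reversed genes were B2m 0.16, Foxp3 0.14, Cxcl9 0.23 and Cxcl10 0.39. Reversed list medians were regulatory T cell 0.34, naive T cell 0.23, B cell 0.068, plasma cell 1.71, macrophage 0.097, dendritic cell 0.015, chemokine 0.25, tertiary lymphoid structure 0.13, type I interferon 0.016, dedifferentiation 0.13, secretion 0.23, oxidative stress 0.048, proliferation 0.070, endothelial 0.081, lymphatic endothelial 0.014 and Schwann cell 0.062. Reversed scores were regulatory T cell 0.24, naive T cell 0.18, B cell 0.32, chemokine 0.20, secretion 0.27, proliferation 0.051, endothelial 0.013 and lymphatic endothelial 0.020. The cause was not tested.

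With limma-voom, Gcg was at -0.020 and Ins1 at 0.093. With the length offset, Gcg was at -0.31, Ins2 at -0.085, the dedifferentiation list at 0.074 and the mitochondrially encoded list at -0.014. With medians over members, the scores of p53, ductal and endothelial lists were 0.33, -0.082 and 0.071, and the cytotoxic to T cell ratio was 0.048. The cause was not tested.

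Macrophage and dendritic cell lists lost their camera call without IgG 1, IgG 6, anti-CD3 2, anti-CD3 3 or anti-CD3 5, and MHC class II without IgG 1, IgG 6, anti-CD3 2 or anti-CD3 3. The T cell list lost it without IgG 6 or anti-CD3 3, MHC class I without IgG 6, and the mitochondrially encoded list without IgG 1 or IgG 6. Of these medians, macrophage was -0.16 without IgG 6 and -0.93 to -0.68 in the other 4, dendritic cell -0.23 and -0.72 to -0.60, MHC class II -0.40 and -1.12 to -1.09, and T cell -0.35 and -0.91. Leaving out 1 library reversed the sign of some values, none of which passed with all libraries. Genes ranged as follows, Cxcl10 -1.45 to 0.088, Gcg -0.048 to 0.15 and Ins1 -0.20 to 0.16. List medians ranged as dedifferentiation -0.13 to 0.21, chemokine -0.65 to 0.19, endothelial -0.31 to 0.061, islet autoantigen -0.14 to 0.048, oxidative stress -0.11 to 0.020, p53 -0.13 to 0.088, plasma cell -0.92 to 1.09, proliferation -0.87 to 0.057 and secretion -0.40 to 0.23. Scores ranged as dedifferentiation -0.10 to 0.25, beta cell -0.17 to 0.012, chemokine -0.58 to 0.025, endothelial -0.27 to 0.0032, islet autoantigen -0.072 to 0.094, naive T cell -0.61 to 0.018, oxidative stress -0.11 to 0.0045, p53 -0.050 to 0.060, regulatory T cell -0.64 to 0.012 and secretion -0.30 to 0.14. The cause was not tested.

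Over all settings, single genes gave 1685 values on the same side of the threshold, 104 that lost it, 30 that gained it and 27 reversed. Lists gave 573, 57, 30 and 59. Scores gave 616 the same, 2 that gained it and 30 reversed, and ratios 197 and 1.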

Other observations

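Tests chosen only after the result was seen are those of the histone, tissue kallikrein, hypoxia response and cytosolic ribosomal protein lists; the CD8 test was fixed before its result.

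Genes of the hypoxia response, a list written after the data were seen, were higher in anti-CD3 islets. Of 23 tested members 22 had positive values, with a median log2 fold change of 0.89, and 16 passed adjusted over the list alone. Over all genes 0 passed edgeR, against 17 at an unadjusted p under 0.05 and 8 with DESeq2. Bnip3, a mitophagy receptor, was at 1.31 ± 0.27, Ddit4, an inhibitor of mTORC1, at 1.25 ± 0.24 and the glycolytic enzyme Pgk1 at 0.89 ± 0.21 (SE, n = 6 per group). The list score had an exact permutation p = 0.0368 with all libraries and p = 0.0667 without IgG 5 and IgG 6, where the median was 0.84. Camera gave an adjusted p = 7.67e-11 over the 4 added lists (adjusted p = 0.0856 with an estimated correlation). Of the 23, Ldha and Hk2 also belong to the disallowed list of beta cells.

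Tissue kallikreins, serine proteases of exocrine glands, were higher in all 6 tested members, with a median of 1.13 and 4 passing adjusted over the list alone. Over all genes 0 of them passed edgeR, against 4 at an unadjusted p under 0.05 and 3 with DESeq2. Klk1b4 was at 1.78 ± 0.40 and Klk1 at 1.13 ± 0.35 (SE, n = 6 per group). The list's camera adjusted p was 2.87e-05 (adjusted p = 0.0856 with an estimated correlation) and the exact permutation p of the score was 0.00433. Without IgG 5 and IgG 6 the median was 0.76 (exact permutation p of the score 0.0190). The score was 3.21 ± 0.99 in IgG and 4.44 ± 0.35 in anti-CD3 (SD, n = 6 each), and it was not set against the acinar score. Histone genes, measured here in poly(A) RNA only, were higher in 18 of 23 members, with a median of 0.48 and 4 passing edgeR. This list was the only one of the 4 to hold with an estimated correlation (adjusted p = 0.0370), and because its leading genes prompted it, that is not independent evidence. All 81 cytosolic ribosomal protein genes were higher, with a median of 0.75 and 79 passing adjusted over the list alone, 0 over all genes with edgeR and 65 with DESeq2. Their camera adjusted p was 1.78e-45 (adjusted p = 0.0791 with an estimated correlation).

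Fewer CD8 T cells per T cell in anti-CD3 was a hypothesis. The mean of Cd8a and Cd8b1 minus that of 5 pan-T genes was -0.18 ± 0.33 in IgG and -0.67 ± 0.57 in anti-CD3 (SD, n = 6 each; exact permutation p = 0.106), which does not decide it.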
